A study of Caenorhabditis elegans with 11 samples.

How the data were processed

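The study measured poly(A)-enriched RNA of whole worms by paired-end sequencing with reads of 73 bp on an Illumina instrument, per the labels' protocols, in 11 libraries of 3 strains, with 1 library per group. The groups were taken from the labels. The glp-4 libraries carry a stage in their titles that differs from their stage field and the design text, and were treated as adults. The deposited tables of these libraries are titled glp-1, while their column names and the labels say glp-4, which was followed. The labels give only a minimum number of reads for all samples, so the depth behind each value is not known more closely and no counting interval is given.

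The deposited data are 6 tables, a higher and a lower list for each strain, which hold only genes that the submitters selected; every gene in them has an unadjusted P-value of at most 0.01 in the authors' deposited comparison. Per the submitters' processing notes, Cufflinks and Cuffdiff were used; their versions, the aligner, the genome build and the annotation are not given in the sources used here. Per the file headers, each table gives an FPKM value for each library (fragments scaled to transcript length and to the number of mapped fragments), a pooled FPKM for the knockdowns of a strain together and 1 for its gfp control, a log2 fold change, a P-value and a q-value. The deposited log2 fold change follows the ratio of the pooled FPKM columns, with 10 exceptions of more than 0.001, and is a placeholder for 72 entries in which a pooled value is 0. A test statistic, a score with no fixed range, is deposited in the file headers of 5 tables and was not used. The pooled columns are scaled differently from the single-library columns: the deposited log2 fold change minus that of the mean knockdown FPKM over gfp had a median of −0.08 in N2, −0.03 in smg-1 and 0.13 in glp-4.

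An FPKM of 0 in a single library can be a failed estimate. In 9 entries a knockdown library is listed at 0 although the pooled knockdown FPKM is above 5, for example col-90 with prp-31 RNAi in N2, and in 18 entries the pooled gfp value is 0 although the gfp library has a value above 0. Such genes are not named for their folds. In all, 61 of the 1106 entries have a 0 in some library.

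From the single-library FPKM, the log2 ratio of knockdown + 1 to gfp + 1 was computed for each gene and knockdown, with a pseudocount of 1 FPKM, so a fold change here is on that scale and understates the change of low genes. With 1 library per group no test was made and no p-value was computed; P and q-values are those of the authors' deposited tables. Table medians, numbers of genes changed at least 2-fold, ratios between knockdowns, overlaps of the lists between strains and differences of the shared genes between N2 and smg-1 were computed. An overlap was set beside the product of the list sizes over the 19985 protein-coding genes of Ensembl annotation release 115 and beside 10000 random draws. For each gene list, the number of members in the higher table was set among 10000 draws of as many genes from both tables of the strain, and a list with at least 3 members was said to lie mostly in a table when it was beyond 97.5 percent of draws. A list's median fold was set among 10000 random lists of the same size, matched on mean FPKM in 5 bins. Percentiles describe these libraries only. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 with a fixed seed of 20. The code was tested on simulated data: for median folds planted in all 6 tables (1106 genes), the largest error of a recovered median was 0.06 on the log2 scale.

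The lists, 19 gene lists and 5 marker lists, were fixed by gene name before the data were examined: RNAi targets and mutated genes, apoptosis, DNA damage response, splicing, nonsense-mediated and mRNA decay, heat shock, unfolded protein response, detoxification, innate immunity, collagens and cuticle, hedgehog-related, lipid metabolism, histones, replication and cell cycle, proteasome, F-box and related, ribosomal proteins, nuclear hormone receptors, small RNA pathway, and markers of germline, muscle, neurons, intestine and hypodermis. Some genes are in more than 1 list. Members were taken by name or name pattern, so a member need not have the function that its list is named for.

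The genes named in the report follow a rule fixed at the same time. In order of priority it takes, for each strain, every listed member of the target, apoptosis and DNA damage lists; in each table, the 8 genes with a public name and no 0 value whose smallest change over the knockdowns is largest; the 3 members with the largest such change of each list with at least 3 members in the table; the 3 genes with the largest spread between knockdowns; the 5 genes found in the same direction in most strains; and the 2 genes with the largest such change, sequence names included. About 30 genes per strain were printed in that order. Members of lists with 5 or fewer genes in a table, shared genes, sip-1, hil-1, col-90 and the genes of the additional observations that lie beyond that limit were named after their values were seen.

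Gene names are those of the tables. By sequence name, 1096 of the 1106 entries matched a RefSeq gene table of assembly WBcel235, which was used only for gene types and numbers: 1037 matched protein-coding genes, 38 pseudogenes and 21 non-coding RNA genes. Positions are the deposited ones. In 51 matched entries the deposited interval equals the gene in that table, so most intervals cover part of a gene or differ from it.

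Alternatives fixed before the data were examined were a pseudocount of 0.1, a pseudocount of 0 without genes at 0, a minimum mean of 1 FPKM, a minimum change of 2-fold or 4-fold in every knockdown, and a background of all 46926 annotated genes. Chosen after seeing the data were the scaling of the pooled comparison, leaving out genes listed at 0, leaving out the prp-31 library, leaving the target prp-31 out of the lists, leaving out the cuticle and hedgehog-related lists in N2, and leaving out the germline list in glp-4. Raw reads and splicing within genes were not analysed here.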

Results

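RNA was sequenced from whole Caenorhabditis elegans after knockdown, by feeding RNA interference (RNAi), of prp-6, prp-8 or prp-31, which encode proteins of the spliceosome's U4/U6.U5 tri-snRNP. The control libraries came from worms fed a clone against gfp, a gene that worms without a GFP transgene do not carry. There were 11 libraries. N2 (wild type) and smg-1(r861), a mutant in a kinase that nonsense-mediated mRNA decay needs, each gave 4 libraries, 1 for each of the gfp, prp-6, prp-8 and prp-31 clones, from larvae at stage L3 fed for 24 h at 20 °C. The temperature-sensitive glp-4(bn2) mutant, in which germ cells fail to proliferate at 25 °C, gave 3 libraries (gfp, prp-8 and prp-31), labelled with a temperature of 25 °C. They came from 5-day adults kept 72 h on OP50 bacteria and then 48 h on the RNAi clones. The titles of these libraries say L3, whereas the stage field and the design text say adult. The tables of this strain are titled glp-1, a different gene, whereas the sample labels and the column names say glp-4. Every group had 1 library, so no difference below has a replicate check, and none is tested. The labels give only a minimum for the reads of a library, so the depth behind each value is unknown. The values are the authors' FPKM for 1106 table entries in 6 lists of genes that they selected as higher or lower in a strain's pooled knockdowns than in its gfp control, so genes outside these lists have no value here. Folds are ratios of FPKM + 1, a scale that understates the change of low genes.

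The knockdown target that the lists contain, prp-31, was below its gfp control in the libraries labelled prp-31 RNAi and above it in those of the other clones. In N2 it had 40.6 FPKM with gfp, 25.3 with prp-31 RNAi, 133 with prp-6 RNAi and 144 with prp-8 RNAi. In smg-1 the values were 31.4, 24.0, 95.3 and 122 FPKM in the same order. The gene lies on chromosome I, and the deposited interval runs from 5127828 to 5129612; the genome build is not given in the sources used here, and many deposited intervals span only part of a gene. Of the list of RNAi targets and mutated genes, prp-31 was the only member in the N2 and smg-1 tables and none was in the glp-4 tables, so the other targets could not be checked.

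The first comparison asks which genes of wild-type L3 larvae differ when a tri-snRNP protein is depleted. In N2, atl-1, the worm homologue of the checkpoint kinase ATR, was higher in all 3 knockdowns. It had 8.17 FPKM with gfp, 32 with prp-6, 55 with prp-8 and 14.7 with prp-31 RNAi (chromosome V, interval 9638428 to 9645502). The apoptosis activator egl-1, a BH3-only gene, was highest after prp-8 RNAi, at 9.41 FPKM against 0.497 with gfp, and had 1.23 FPKM with prp-6 and 1.02 with prp-31 RNAi (chromosome V, 14432290 to 14432359). The apoptosis gene ced-11 was 3.71-fold, 2.10-fold and 1.96-fold higher with prp-6, prp-8 and prp-31. These 3 genes were all the members of the apoptosis and DNA damage lists in the N2 tables. From the table sizes, 1.72 of the 2 apoptosis genes and 0.861 of the 1 DNA damage gene were expected in the higher table. In the authors' deposited table, the pooled gfp value of egl-1 is listed at 0, so its deposited fold is not finite.

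By the smallest change over the knockdowns, fbxa-163 and gst-24 were among the N2 genes with the largest changes. The F-box gene fbxa-163 was 27.1-fold higher with prp-6, 45.2-fold with prp-8 and 2.43-fold with prp-31 RNAi, from 0.334 FPKM with gfp. The glutathione S-transferase gene gst-24 went from 26.4 FPKM to 263, 523 and 62.4 FPKM in the same order. The kinesin cargo adaptor gene kca-1 was 3.50-fold, 6.02-fold and 2.10-fold higher, and hacd-1, a hydroxyacyl-CoA dehydrogenase gene, 3.38-fold, 5.85-fold and 2.04-fold. The chemoreceptor gene srr-6 was higher by 3.93-fold, 2.09-fold and 2.86-fold. Of the detoxification list, 9 genes were in the N2 higher table, against 9.47 expected from the table sizes, and 2 in the lower table; besides gst-24, cyp-37B1 was 4.55-fold, 2.48-fold and 1.77-fold higher and gst-10 3.28-fold, 2.02-fold and 1.49-fold. Of the innate immunity list, 12 were in the higher table, against 11.2 expected, and 1, hpo-24, was in the lower; the lysozyme gene lys-1 had 466 FPKM with gfp and 1107, 2147 and 640 FPKM with prp-6, prp-8 and prp-31, dod-3 had 28.8 and then 161, 111 and 57.6 FPKM, and lys-3 was 2.89-fold, 1.85-fold and 2.24-fold higher. With prp-8, 4 of these 12 genes were below gfp, among them clec-230 (11.5 FPKM with gfp and 2.93 with prp-8) and nlp-34 (32.2 and 11.2 FPKM), chosen after their values were seen. Of the F-box and related list, 4 genes were in the higher table and 2 in the lower.

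Of the splicing list, the N2 higher table held 7 genes besides the target prp-31, against 6.89 expected from the table sizes, and the lower table a single member, the cyclophilin gene cyn-9 (8.66 FPKM with gfp and 3.18, 2.96 and 4.29 with prp-6, prp-8 and prp-31). The Sm protein gene snr-5 had 68.2 FPKM with gfp and 200, 193 and 109 FPKM in the knockdowns, the DEAD-box helicase gene ddx-23 27.8 and then 93.3, 102 and 43.3 FPKM, and prp-38 18.4 and then 55.7, 70.2 and 28 FPKM. The median log2 fold of the 7 genes was 1.53 with prp-6, 1.62 with prp-8 and 0.58 with prp-31.

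Cuticle genes in the N2 higher table differed between the clones. The table held 46 genes of the collagen and cuticle list, against 43.1 expected from the table sizes, with median log2 folds of 2.53 for prp-6, −0.38 for prp-8 and 1.01 for prp-31, and 16 hedgehog-related genes, with medians of 2.54, −0.25 and 0.91. With prp-8 RNAi, 33 of the 46 cuticle genes were below gfp. Over the whole N2 higher table, 279 genes were above gfp with prp-8 and 130 were at or below it. Values below gfp with prp-8 were therefore not confined to the cuticle list. Of the table's genes, 46 were at least 2-fold below gfp with prp-8, and only 9 of the cuticle list were. The prp-8 median of the cuticle list was below that of all 10000 random lists of the same size and expression from the table (0 percent lower), and the prp-6 median was above 99.3 percent of them. The hedgehog-related medians were above 89.4 percent of such lists with prp-6 and above 4.34 percent with prp-8, so that list did not stand apart by itself. The collagen gene sqt-1 had 170 FPKM with gfp, 1372 with prp-6, 238 with prp-8 and 237 with prp-31 RNAi; the hedgehog-related gene grl-15 had 27.3, 338, 47.1 and 43.9 FPKM and grl-7 20.6, 208, 28.3 and 41.3 FPKM. The patched-related gene ptr-17, which is in both lists, was 5.51-fold, 1.57-fold and 1.61-fold higher, and cut-6 2.04-fold, 2.36-fold and 1.41-fold. The 5 genes of the unfolded protein response list in the table were all abu and pqn genes. Their medians were 2.97 with prp-6, −0.14 with prp-8 and 1.13 with prp-31, the first above 90.4 and the second above 25.4 percent of random lists; pqn-32 was 10.6-fold higher with prp-6 and 1.70-fold with prp-8, abu-13 8.55-fold and 1.17-fold, and pqn-13 5.52-fold higher and 0.905-fold.

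**Figure D1:**
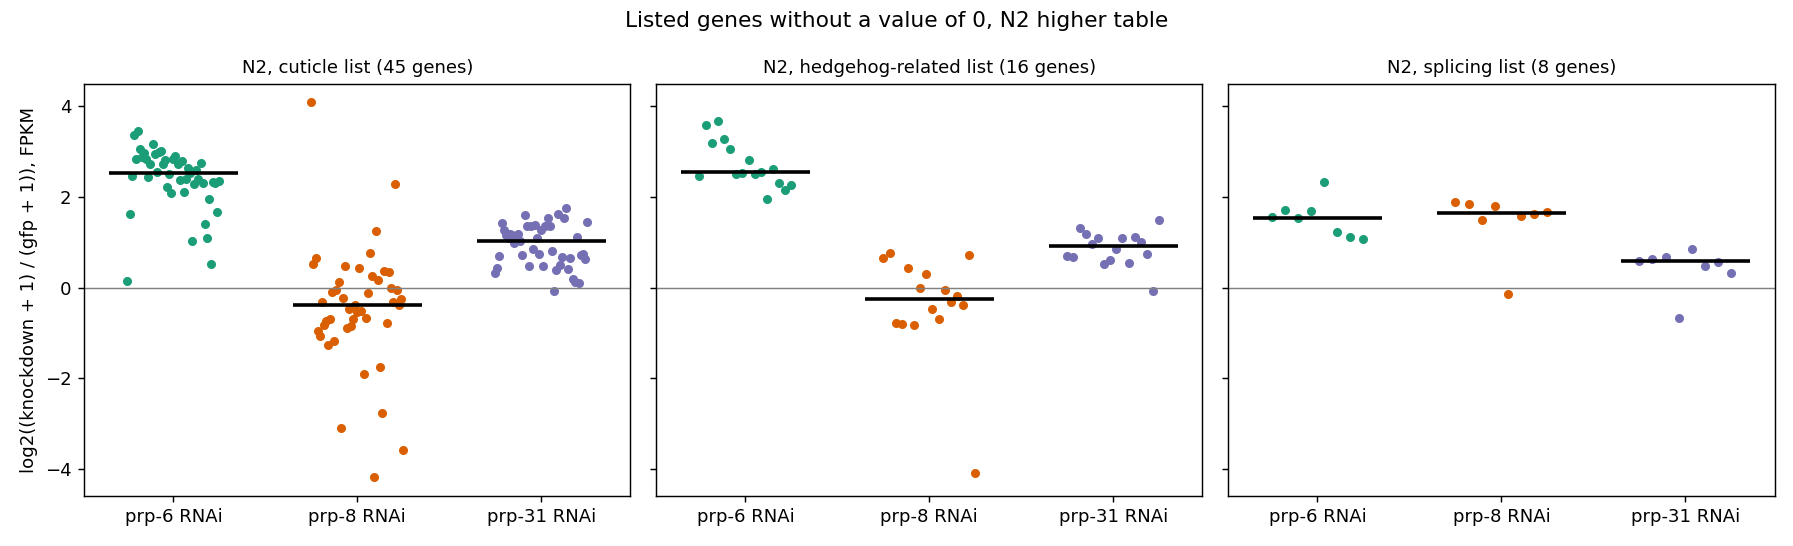
Log2 fold against gfp RNAi, on the FPKM + 1 scale, of N2 genes of the cuticle, hedgehog-related and splicing lists that were in the higher table and had no value of 0; each point is a gene and each bar the median. The cuticle medians were 2.51 with prp-6, −0.38 with prp-8 and 1.03 with prp-31 over 45 genes, whereas the splicing medians, prp-31 included, were 1.54, 1.64 and 0.58.

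Among the N2 genes listed as lower, the Piwi gene prg-2 had 19.8 FPKM with gfp and 2.83, 2.69 and 8.64 with prp-6, prp-8 and prp-31. The aquaporin gene aqp-8 had 118 FPKM with gfp and 21.2, 46.5 and 65.8 in the knockdowns. The nuclear hormone receptor gene nhr-155 was 3.48-fold, 3.68-fold and 2.12-fold lower, the NAB cofactor gene mab-10 2.68-fold, 1.77-fold and 2.74-fold, fbxa-72 3.38-fold, 2.24-fold and 2.07-fold, and the non-coding RNA linc-72 2.59-fold, 5.09-fold and 1.90-fold. The cuticle list had 4 lower members, among them bus-1 at 3.33 FPKM with gfp and 1.11, 1.30 and 0.472 in the knockdowns. For the N2 tables as a whole, the higher genes had median log2 folds of 2.05, 0.65 and 0.67 with prp-6, prp-8 and prp-31, and the 66 lower genes −1.59, −1.39 and −0.69. In every knockdown alike, 11 of the higher and 8 of the lower genes were at least 2-fold changed; with a pseudocount of 0.1 these counts were 61 and 15, and without the prp-31 library 122 and 56. In the authors' deposited tables, 34 of the higher and 2 of the lower N2 genes had a q-value below 0.05, and every listed gene had an unadjusted P of at most 0.01.

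The second comparison makes the same contrast in larvae that lack nonsense-mediated decay. In smg-1, atl-1 had 6.43 FPKM with gfp and 23.3, 50.6 and 12.8 with prp-6, prp-8 and prp-31 RNAi, and egl-1 had 0.501, 0.963, 7.11 and 0.507 FPKM. The double-strand break repair gene rad-50 was 2.78-fold, 4.23-fold and 2.35-fold higher. The apoptosome gene ced-4 was 1.59-fold, 2.34-fold and 1.30-fold higher, ced-8 1.86-fold, 2.10-fold and 1.15-fold, and ced-11 2.39-fold, 1.53-fold and 1.16-fold. Together these were the 4 apoptosis and the 2 DNA damage genes in the smg-1 tables, all in the higher table. From the table sizes 2.85 and 1.43 were expected there, and 73.8 and 48.6 percent of draws had fewer. Every member was in the higher table, so these are the largest percentages that lists of this size can reach. The draws therefore could not set either list apart. In the authors' deposited comparison the q-values were 0.068 for ced-11, 0.184 for ced-8, 0.198 for ced-4 and 0.262 for egl-1, and 0.00821 for atl-1 and rad-50.

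Among the large folds in smg-1 were again those of fbxa-163 (26.6-fold, 54-fold and 3.19-fold with prp-6, prp-8 and prp-31) and of gst-24 (22.9 FPKM with gfp and 211, 379 and 56.1 FPKM in the knockdowns). The heat shock gene hsp-70 was 2.61-fold, 2.40-fold and 2.06-fold higher, lpd-6 2.60-fold, 2.85-fold and 2.04-fold, and mrpr-1 4.32-fold, 8.90-fold and 2.32-fold. All 11 members of the splicing list in the smg-1 tables were in the higher table, more than in 97.9 percent of random draws. Without the target prp-31 it was 10 members, again all higher, and 96.8 percent, short of the bound set for a list. A list of 10 cannot score more in these tables, so falling short follows from its size. Of the splicing members, ddx-23 was 2.77-fold, 3.79-fold and 1.60-fold higher, the helicase gene snrp-200 2.32-fold, 3.25-fold and 1.55-fold, and mog-5 2.32-fold, 3.36-fold and 1.54-fold. Of the detoxification list 7 genes were in the higher and 4 in the lower table; pgp-1 was 2.78-fold, 3.00-fold and 2.03-fold higher and gst-15 3.46-fold, 6.07-fold and 1.73-fold. Of the innate immunity list 11 were in the higher and 2 in the lower table, and with prp-8 1 of the 11 was below gfp, at a log2 fold of −0.79. The C-type lectin gene clec-265 had 10.9 FPKM with gfp and 23.7, 74.4 and 19.6 in the knockdowns, lys-2 200 and then 332, 601 and 288, and lys-1 481 and then 1000, 1909 and 672 FPKM. Of the F-box and related list 9 were higher and 3 lower.

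**Figure D2:**
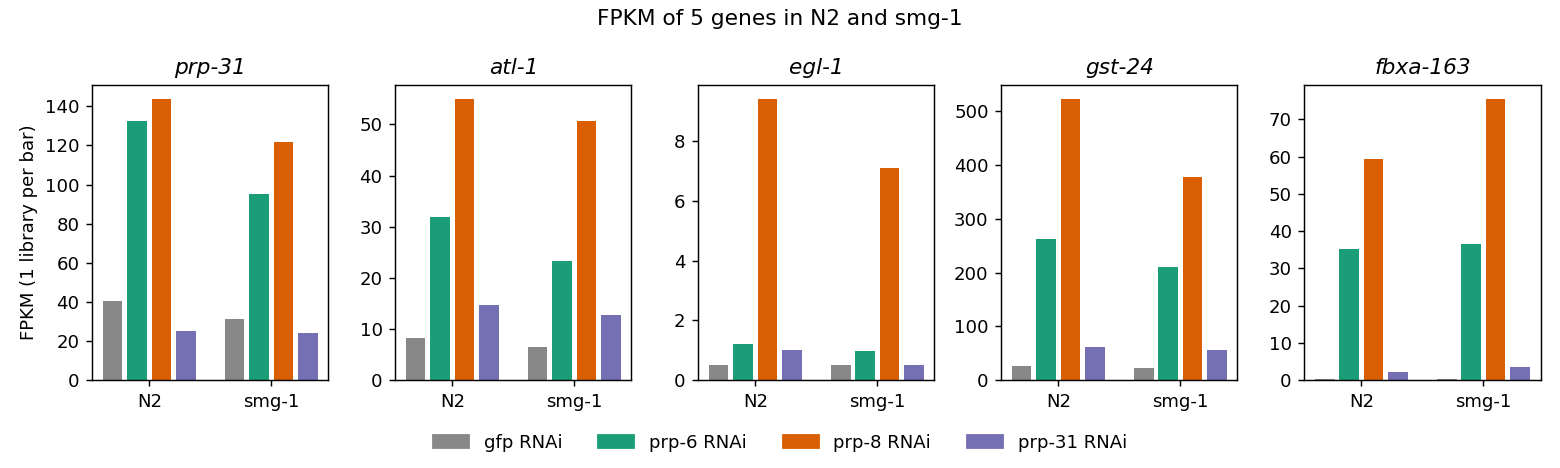
FPKM of prp-31, atl-1, egl-1, gst-24 and fbxa-163 in the N2 and smg-1 libraries, 1 library per bar on linear axes that start at 0 and differ between panels. In both strains prp-8 RNAi gave the highest bar of each gene, for example 55 FPKM of atl-1 in N2 and 50.6 in smg-1.

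Core histone genes were lower in smg-1. The smg-1 lower table held 14 histone genes, and the higher table a single member, the linker histone gene hil-1; 100 percent of 10000 random draws put more of them in the higher table. Their median log2 fold was −1.96 with prp-6, −2.68 with prp-8 and −1.51 with prp-31. The gene his-3 had 33.5 FPKM with gfp and 7.14, 1.96 and 8.34 in the knockdowns, his-38 24.4 and then 3.33, 2.67 and 4.15, his-18 14 and then 2.77, 0.840 and 3.01, his-59 16.5 and then 3.43, 1.33 and 3.99, and his-40 21.6 and then 4.53, 1.49 and 5.92; his-2 was 3.24-fold, 5.33-fold and 3.43-fold lower and his-4 3.39-fold, 5.96-fold and 2.87-fold. Histone genes have near-identical copies whose reads the authors' estimates could split, so values of single copies are uncertain. In the same libraries the ribosomal RNA genes rrn-2.1 and rrn-1.2 were higher, rrn-2.1 at 4034 FPKM with gfp and 36295, 34627 and 12191 with prp-6, prp-8 and prp-31, and rrn-1.2 by 20.1-fold, 20.8-fold and 3.00-fold, although the libraries were enriched for poly(A) RNA. The folds of rrn-1.2 are uncertain, because its deposited pooled FPKM, 3.41 for the knockdowns and 0.245 for gfp, is too low for folds of 20.1 and 20.8. Of the germline markers in smg-1, 4 were in the lower and 1 in the higher table, and 97.4 percent of draws had more in the higher table. The lipase-like gene lips-6 was 3.25-fold, 3.69-fold and 3.46-fold lower. Cuticle genes were split in smg-1, with 4 in the higher and 7 in the lower table (the higher count was below 98.3 percent of draws, and below 95.6 percent among genes with a mean of at least 1 FPKM).

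For the smg-1 tables as a whole, the 346 higher genes had median log2 folds of 0.89, 1.57 and 0.40 with prp-6, prp-8 and prp-31, and the 139 lower genes −1.08, −1.32 and −0.70. At least a 2-fold change in every knockdown was seen for 16 of the higher and 26 of the lower genes, for 43 and 34 with a pseudocount of 0.1, and for 122 and 61 without the prp-31 library. In the authors' deposited tables, 130 of the higher and 37 of the lower genes had a q-value below 0.05.

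The third comparison follows prp-8 and prp-31 knockdown in glp-4 adults. Oocyte and germline genes were lower, mostly with prp-8 RNAi. The lower table held 10 genes of the germline marker list and the higher table none, with a median log2 fold of −2.59 with prp-8 and −0.36 with prp-31. The oocyte surface gene egg-1 had 28.8 FPKM with gfp, 2.57 with prp-8 and 19.9 with prp-31 RNAi, the Pumilio-family gene puf-11 20.8, 2.47 and 13.7 FPKM, and gld-3 7.05, 1.06 and 4.87 FPKM. In the authors' deposited comparison the q-values of egg-1, puf-11 and gld-3 were 0.223, 0.222 and 0.664. More of the list was in the lower table than in 99.6 percent of draws. In the same prp-8 library the ribosomal RNA gene rrn-2.1 was 258-fold higher than with gfp, against 9.33-fold with prp-31. The ribonucleotide reductase gene rnr-2, the DNA damage list's member here, had 37.6, 9.69 and 27.9 FPKM, and the mitotic cyclin gene cyb-2.2, 1 of 4 lower members of the replication and cell cycle list, 17.8, 1.93 and 11.2 FPKM; cdc-25.2 was 2.66-fold and plk-3 3.24-fold lower with prp-8. The C-type lectin genes clec-87 and clec-88 were 7.88-fold and 5.67-fold lower with prp-8, and 1.32-fold and 1.36-fold with prp-31, and the saposin-like gene spp-9 had 646, 70.9 and 407 FPKM; the innate immunity list had 6 genes in each glp-4 table. Of the F-box and related list 9 genes were lower and none higher, more than in 99.1 percent of draws and in 97.2 percent among genes with a mean of at least 1 FPKM; skr-8, skr-9 and skr-15, members of a gene family that can share reads, were 3.48-fold, 3.82-fold and 3.61-fold lower with prp-8.

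Of the 4 heat shock genes listed as lower in glp-4, 3 were lower with prp-31 than with prp-8 RNAi. The gene hsp-70 had 98.6 FPKM with gfp, 51.6 with prp-8 and 21.1 with prp-31 RNAi, hsp-16.41 had 150, 63.0 and 33.9 FPKM, and hsp-16.2 had 121, 62.0 and 34.1 FPKM. The fourth gene, sip-1, went the other way, with 111, 18.5 and 97.2 FPKM. The list's median log2 fold was −1.10 with prp-8 and −1.95 with prp-31. The collagen genes col-125, dpy-14 and dpy-13 were 2.62-fold, 3.10-fold and 2.11-fold lower with prp-8 and 2.36-fold, 2.15-fold and 2.30-fold with prp-31, from low values; the cuticle list had 5 lower and 3 higher members, and 2 lower ones with a mean of at least 1 FPKM. Of the higher ones, col-124 had 228, 483 and 316 FPKM with gfp, prp-8 and prp-31, col-51 was 1.91-fold and 1.35-fold higher, and col-80 was 2.19-fold higher with prp-8 and 0.985-fold with prp-31, a value whose direction turns under the pooled scaling. The short-chain dehydrogenase gene dhs-8 was 1.99-fold and 2.41-fold lower, and the transthyretin-like gene ttr-50 6.40-fold and 2.17-fold.

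**Figure D3:**
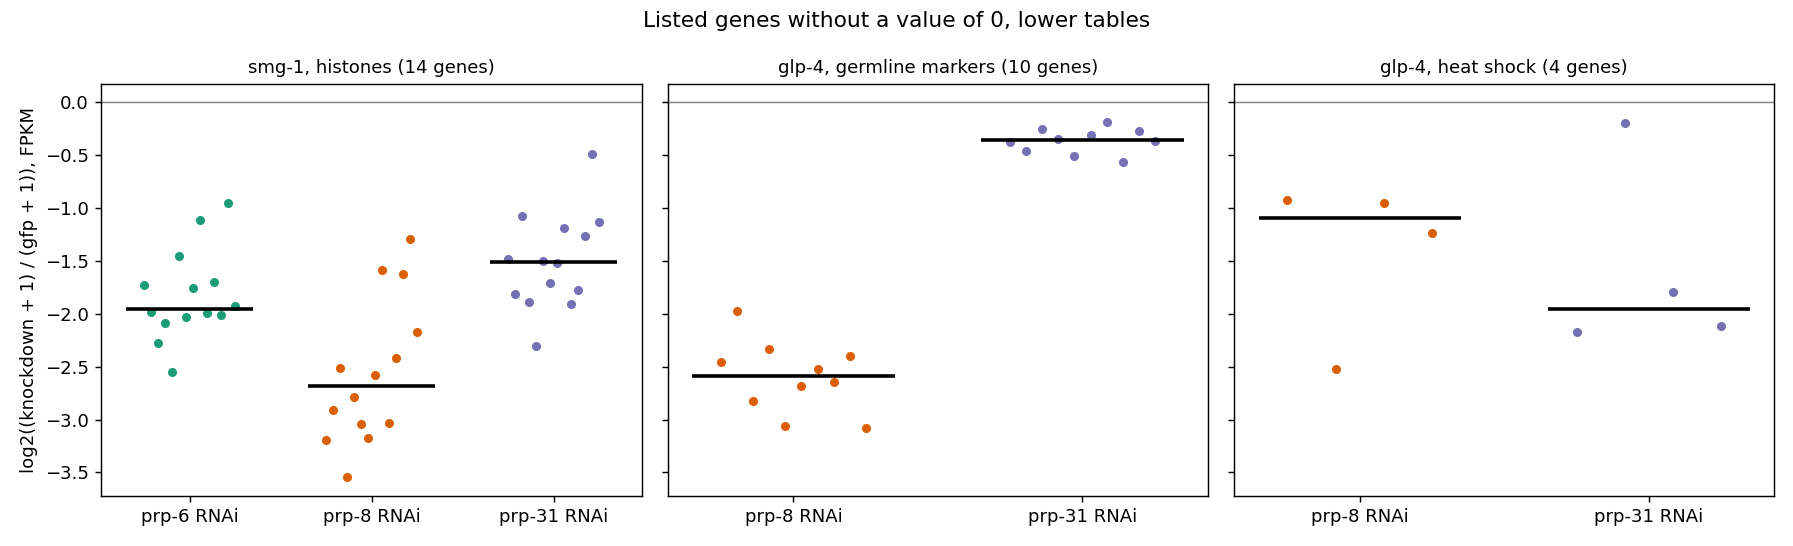
Log2 fold against gfp RNAi, on the FPKM + 1 scale, of the genes of 3 lists in the lower tables that had no value of 0; each point is a gene and each bar the median. The smg-1 histones had medians of −1.96, −2.68 and −1.51 with prp-6, prp-8 and prp-31, the glp-4 germline markers −2.59 and −0.36 with prp-8 and prp-31, and the glp-4 heat shock genes −1.10 and −1.95.

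Cytochrome P450 genes were among the glp-4 genes listed as higher. The detoxification list had 9 higher and 1 lower members, more in the higher table than in 99.8 percent of draws. Of the 9, 0 were at least 2-fold changed in both knockdowns. Only 3 of all 58 higher genes were, so that minimum cannot decide about the list. The gene cyp-35B2 was 1.78-fold and 2.31-fold higher with prp-8 and prp-31, cyp-35B1 1.65-fold and 1.93-fold, cyp-33C1 2.02-fold and 1.66-fold, and cyp-13A6 2.16-fold and 1.58-fold. The lectin gene clec-258 had 106 FPKM with gfp and 200 and 228 with prp-8 and prp-31, ilys-3, an invertebrate lysozyme gene, 61.2 and then 99.7 and 96.3, scl-11 9.78 and then 17.4 and 24.1, and clec-227 0.427 and then 1.57 and 1.08 FPKM. The ribosomal RNA gene rrn-2.1 had 397 FPKM with gfp, 102770 with prp-8 and 3716 with prp-31 RNAi. The 58 higher genes had median log2 folds of 0.75 and 0.70 with prp-8 and prp-31 and the 88 lower genes −1.94 and −0.49; adding the 0.13 log2 shift between the single-library scale and that of the authors' pooled values changes no sign. At least a 2-fold change in both knockdowns was seen for 3 higher and 6 lower genes, for 9 and 26 with a pseudocount of 0.1, and with prp-8 alone for 15 and 76. In the authors' deposited tables, 7 higher and 5 lower genes had a q-value below 0.05. The q-values of both glp-4 lists reached 0.925, against 0.305 in N2 and 0.310 in smg-1. By that comparison many of the listed glp-4 genes may be false positives.

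**Figure D4:**
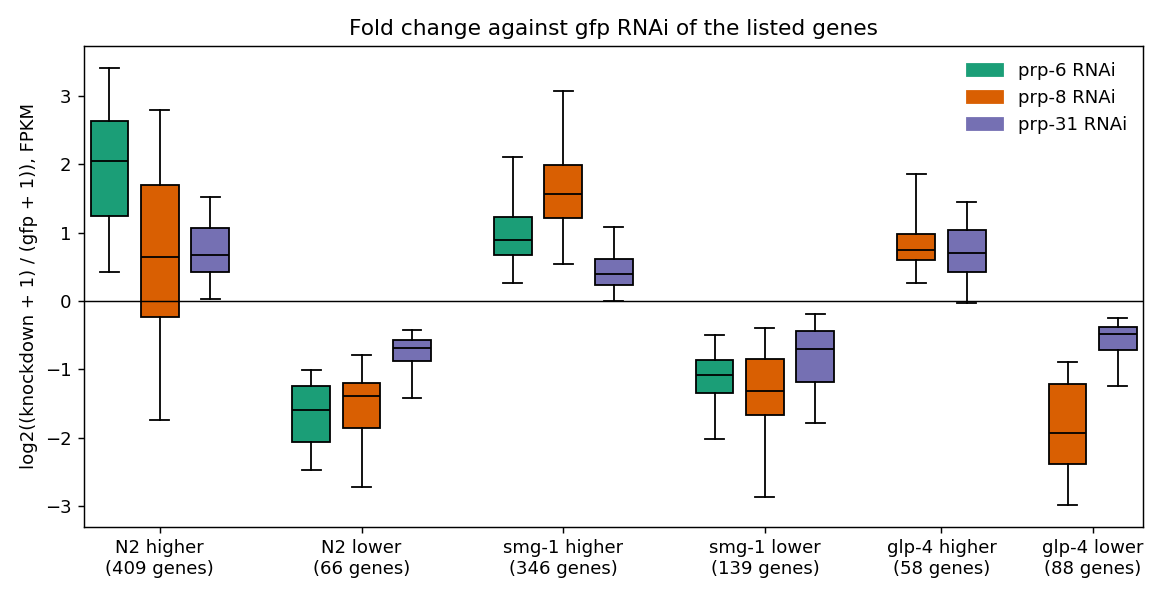
Log2 fold against gfp RNAi, on the FPKM + 1 scale, of all genes in each of the 6 tables; boxes span the quartiles with the median as a line, and whiskers the 5th to 95th percentile. The N2 higher genes had medians of 2.05 with prp-6 and 0.65 with prp-8, and the smg-1 higher genes 0.89 and 1.57.

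Set against each other, the clones ranked differently in the tables of N2 and smg-1, which hold different genes. In N2, prp-6 gave the largest fold for 251 of the higher genes, prp-8 for 155 and prp-31 for 3, and the median log2 ratio of prp-8 to prp-6 was −1.43. Outside the 56 cuticle and hedgehog-related genes that ratio was −0.61, so its size in N2 depends on those lists. In smg-1, prp-8 gave the largest fold for 308 of the 346 higher genes, and the same ratio was 0.60. Over the 124 higher genes that both strains list, the order was the same, with median log2 folds of 1.28, 1.92 and 0.47 in N2 and 1.12, 1.79 and 0.40 in smg-1 for prp-6, prp-8 and prp-31. Among lower genes it was 0.00 in N2 and −0.21 in smg-1. The prp-31 library lay nearer to gfp than the prp-6 library, with median log2 ratios of prp-31 to prp-6 of −1.20 and 0.85 for the N2 higher and lower genes and −0.48 and 0.35 in smg-1. Only the target prp-31 has values, and its own clone lowered it only in part. How far each clone depleted its target therefore cannot be compared, nor told apart from the ranking of the clones. The ratio of prp-31 to prp-8 was 0.03 and 0.78 for the N2 higher and lower genes, −1.16 and 0.60 in smg-1, and −0.12 and 1.5 in glp-4. The knockdowns of a strain share 1 gfp library and the genes were chosen on their pooled values, so part of their common direction may come from that control.

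The lists of N2 and smg-1, whose libraries are separate, shared 124 higher genes, among them atl-1, egl-1, ced-11, prp-31, ddx-23, prp-38, gst-24, fbxa-163 and lys-1. Lists of the same sizes drawn from the 19985 annotated protein-coding genes would share 7.08, and the most in 10000 draws was 19. They shared 17 lower genes, including nhr-155, mab-10 and the histone gene his-32, against 0.459 by chance. N2 and glp-4 shared 4 higher genes (C50F7.5, F55G11.4, lys-4 and ora-1) and 5 lower genes (C08F8.3, T05F1.2, hpo-24, spn-4 and wago-1), against 1.19 and 0.291 by chance, and smg-1 and glp-4 shared 7 and 2 (1 and 0.612 by chance). In opposite directions, 6 genes were higher in N2 and lower in smg-1, mlt-10 and grl-5 among them (2.84 by chance), and no gene was lower in N2 and higher in smg-1. The chance values count genes that may not be expressed at all, which makes them too small. No shared gene of the N2 and smg-1 higher lists was 4-fold changed in every knockdown of both, and 4 were 2-fold changed.

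The genes shared by N2 and smg-1, which were selected as changed the same way in both, were compared clone by clone. Over the 124 higher genes, the median of the log2 fold in smg-1 minus that in N2 was −0.19 for prp-6, −0.08 for prp-8 and −0.02 for prp-31; with prp-6, 83 of the 124 had a smaller log2 fold in smg-1. Over the 17 lower genes it was 0.36, 0.10 and 0.32, so the median decrease with prp-6 was smaller in smg-1. Across the 124 genes, which are not independent replicates, Pearson's r between the strains was 0.623 for prp-6, 0.806 for prp-8 and 0.245 for prp-31. The N2 prp-31 folds had a higher r with those of prp-6 (0.375) and prp-8 (0.426) in smg-1 than with those of prp-31.

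The other lists had few members in the tables, which are named here after their values were seen; higher and lower mean the table that lists them, not each library. Of the lipid list, acdh-6, acs-20, lips-7 and lips-9 were in the higher table of N2, although 3 of the 4 were below gfp with prp-8 (median log2 fold −0.73), vit-6, lips-11 and fil-1 higher and lips-6, lips-9 and acs-7 lower in smg-1, and cpt-3 higher in glp-4. Of the nuclear hormone receptors, nhr-25 and nhr-220 were in the higher and nhr-155 in the lower table of N2, nhr-201 and nhr-220 in the higher and nhr-155 and nhr-172 in the lower table of smg-1, and nhr-2 in the lower table of glp-4. Of the small RNA list, prg-2 and wago-1 were lower in N2, and wago-1 and hrde-1 were lower in glp-4. The gene dct-5, a member by its name pattern only and below gfp with prp-8, was in the higher table of smg-1. Of the replication and cell cycle list, cdc-25.1 and plk-2 were lower in N2 and cdk-1 in smg-1, and of the histones, hil-7 was higher and his-32 lower in N2. The decay list had 1 higher gene in smg-1, smgl-2, the ribosomal protein list 1 lower gene in smg-1, rla-2, and the heat shock list 1 higher gene in smg-1, hsp-70. The unfolded protein response list had hsp-70 and pqn-63, the latter below gfp with prp-8, in the higher table of smg-1 and hsp-70 lower in glp-4, and the hedgehog-related list wrt-8 higher and grl-5 and wrt-6 lower in smg-1. Of the germline markers, cpg-2 was higher and glh-2 and msp-64 lower in N2, and in smg-1 cpg-2 was higher and cpg-9, htp-1, htp-2 and syp-1 lower. Of the intestine markers, aqp-8 was lower in N2, vit-6 and cth-1 were higher in smg-1 and cth-1 and cpr-2 higher in glp-4. Of the hypodermis markers, rol-6, nhr-25 and che-14 were in the higher table of N2, with rol-6 just below gfp with prp-8. The tables held no proteasome or muscle gene of the lists.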

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

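Genes whose knockdown libraries all lay on 1 side of gfp in a strain, and all on the other side in another strain, are given here; the difference between strains was not tested, and the strains also differ in stage, temperature and feeding where glp-4 is concerned. The eggshell proteoglycan gene cpg-2 was higher in every knockdown of N2 and smg-1 and lower in both of glp-4, with a median log2 fold 2.5 above that of glp-4 in N2 and 2.37 above it in smg-1. Its FPKM went from 5.21 with gfp to 11.4, 17.8 and 9.34 with prp-6, prp-8 and prp-31 in N2, and from 83.3 to 12.1 and 67.2 with prp-8 and prp-31 in glp-4. The heat shock gene hsp-70 had a median log2 fold 2.81 higher in smg-1 than in glp-4; it had 3.40 FPKM with gfp and at least 8.06 in each knockdown of smg-1, against 98.6 with gfp and 51.6 and 21.1 in glp-4. The gene C38C6.3 had a median log2 fold 1.94 higher in N2 than in smg-1, with 3.77 FPKM with gfp and 49.8, 5.61 and 9.60 with prp-6, prp-8 and prp-31 in N2, and 37.5, 29.4, 21.3 and 11 in smg-1. For Y75B8A.3 the median log2 fold in N2 minus that in glp-4 was −2.39; it had 45.5, 11.4, 8.32 and 30.6 FPKM in N2, and 28.5 with gfp, 34.3 with prp-8 and 46.8 with prp-31 in glp-4.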

How the results depend on the processing

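With 1 library per group, a value counts as kept here when it has the same sign and lies within 1.5 times of its reported value. Of the recomputed values 189 were kept, 79 moved and none changed sign. Counts and chance overlaps cannot change sign. Of the moved values, 43 come from the 2-fold minimum, under which gene counts can only fall, and 6 from the larger background. The tally is therefore no measure of stability. Scaling to the pooled comparison and leaving out genes listed at 0 moved no table median of the folds. Nor did leaving out the cuticle and hedgehog-related lists or the germline list. All of these were chosen after seeing the data. The median log2 ratio of prp-8 to prp-6 in the N2 higher genes did move, from −1.43 to −0.61 outside the 56 cuticle and hedgehog-related genes. A pseudocount of 0.1 raised the N2 higher prp-8 median to 1.04, and a pseudocount of 0 put the glp-4 lower prp-8 median at −2.94, since a pseudocount of 1 shrinks low values. The pseudocount of 0.1 gave 61 (N2 higher), 15 (N2 lower), 43 (smg-1 higher), 9 (glp-4 higher) and 26 (glp-4 lower) genes at least 2-fold changed in every knockdown. Leaving out the prp-31 library, also chosen after seeing the data, gave 122 and 56 in N2, 122 and 61 in smg-1 and 15 and 76 in glp-4, higher and lower. With the pseudocount of 0.1, the smg-1 minus N2 difference became −0.15 (prp-8) and −0.10 (prp-31) for higher and 0.19 (prp-8) for lower genes. The minimum of 1 FPKM gave a median log2 ratio of 0.06 for prp-31 over prp-8 in the N2 higher genes and −0.03 for prp-8 over prp-6 in the N2 lower genes, both near 0 as reported. Requiring a 2-fold change in every knockdown left 4 higher and 1 lower genes shared by N2 and smg-1, 0 and 0 by N2 and glp-4, and 1 and 0 by smg-1 and glp-4; requiring 4-fold left 0 in each case, as fewer genes enter. The background of all annotated genes lowered the chance overlaps of higher and lower genes to 3.02 and 0.195 for N2 and smg-1, 0.506 and 0.124 for N2 and glp-4, and 0.428 and 0.261 for smg-1 and glp-4. Of the lists said to lie mostly in a table, the 2-fold minimum kept 0 in the smg-1 higher, 1 in the smg-1 lower (histones), 0 in the glp-4 higher and 0 in the glp-4 lower table, and the minimum of 1 FPKM kept 1 in the smg-1 lower (histones) and 1 in the glp-4 lower table (germline markers). The 2-fold minimum left only 3 higher and 6 lower genes in glp-4, too few to decide about its lists. Leaving the target prp-31 out of the lists, chosen after seeing the data, left 0 in the smg-1 higher table, since the splicing list then has a member fewer, and gave 3 in the smg-1 lower table. The list added there is the germline markers, which random draws put at either side of the bound, whereas the exact percentages are 97.46 with and 97.44 without prp-31. Of the 8 genes that the rule names first in a table, a pseudocount of 0.1 would name 3 in the N2 higher and 4 in the glp-4 lower table. A fit of strain and clone over the N2 and smg-1 libraries was not run; the genes with values in both strains had been selected as changed in both. Values below 1 FPKM, 479 of those above 0 in the tables, are the least certain, and the number of reads behind them is unknown.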

Other observations

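All tests of explanations in this part were chosen after the results were seen, and the genes named in its first paragraph were named after their values were seen. The genes C50F7.5 and F55G11.4 were the only ones in the higher tables of all 3 strains. C50F7.5 had 21.7, 28.3, 466 and 20.9 FPKM with gfp, prp-6, prp-8 and prp-31 in N2, 28.9, 81.8, 216 and 39.3 in smg-1, and 121, 308 and 183 with gfp, prp-8 and prp-31 in glp-4. F19B10.13 was 24.3-fold, 36.1-fold and 3.06-fold higher with prp-6, prp-8 and prp-31 in N2, and 15.8-fold and 27.7-fold with prp-6 and prp-8 in smg-1. Among genes with no value of 0, the largest spreads between clones in N2 were those of K01D12.9 (67.8 FPKM with gfp and 282, 0.839 and 224 with prp-6, prp-8 and prp-31), R12E2.15 (197, 1603, 13 and 604 FPKM) and the collagen gene col-54 (74.2, 428, 3.18 and 229 FPKM). Another collagen gene, col-101, went the other way, with 1.08, 1.32, 34.1 and 1.60 FPKM in N2 and 2.55, 3.15, 26.3 and 3.36 in smg-1. Of the neuron marker list, 8 genes were in the higher and 1 in the lower table of N2, 7 and 0 in smg-1, and 1 and 1 in glp-4; the insulin-like gene ins-35 had 19.4, 63.8, 75.1 and 27.6 FPKM in N2. Of the germline markers in smg-1, a list so near the bound set for a list (97.4 percent) that a small change decides its side, cpg-2 was in the higher table, and htp-2 was lower by 2.12-fold, 2.74-fold and 1.41-fold and syp-1 by 1.85-fold, 2.06-fold and 1.32-fold with prp-6, prp-8 and prp-31.

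Cuticle and hedgehog-related genes of N2 were higher with prp-6 and mostly not with prp-8. A different scaling of the prp-8 or prp-6 library is argued against, because the median log2 ratio of prp-8 to prp-6 was −2.94 for the 56 members and −0.61 for the other genes of the table, a difference of −2.34; 95 percent of random lists of that size had medians from −2.46 to −0.17. Values near 0 are argued against too, since the 24 members with at least 10 FPKM with gfp and no 0 had a median ratio of −3.21 and none was above −1.45, and the 17 of them that also had at least 10 FPKM with prp-8 had a median of −2.81. Above gfp with prp-6 and below it with prp-8 were 39 of the 56 members, a count that restates the split and favours no explanation of it. Worms at different points of the moulting cycle may account for the split, but no value measures stage. That explanation and an effect of the clones themselves cannot be told apart with 1 library of each.

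Core histone genes were lower in smg-1 in all 3 knockdowns. Less carry-over of RNA without a poly(A) tail would lower ribosomal RNA too, but both listed ribosomal RNA genes were above gfp in every knockdown, by log2 folds of 1.59 to 4.38. Both were seen only because they were selected as higher, and other ribosomal RNA genes have no value. The folds of rrn-1.2 are also uncertain, as its deposited pooled FPKM is only 3.41 for the knockdowns and 0.245 for gfp. These values therefore argue only weakly against that explanation, which stays open. Reads moved between histone copies stay open: the summed FPKM of the 14 listed genes was below gfp in every knockdown, by a log2 ratio of −1.34 at the least, but the list covers 14 of 82 annotated histone genes. Fewer cells in S phase could also lower histone mRNA, but the replication and cell cycle list has only 1 more gene in the lower than in the higher table, cdk-1. Fewer cells in S phase therefore cannot be told apart from the other explanations. Germline markers lay lower too, 4 against 1 (97.4 percent of draws had more in the higher table), so a smaller share of dividing germ cells was not excluded.

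Germline genes were lower with prp-8 in glp-4, a strain whose germ cells should be few at 25 °C. A different scaling of the prp-8 library stays open: without a pseudocount the median log2 ratio to gfp of the 10 members differed by −0.08 from that of the other 77 genes of the lower table, and the higher table had a median of 0.84, but both tables were selected for their direction. The same library had 258 times the gfp value of the ribosomal RNA gene rrn-2.1, and what that means for the other values was not tested. A smaller share of animals or tissue with germline in the knockdown libraries is a candidate explanation, as 1 source would lower all its transcripts by 1 ratio. The members' log2 ratios had an SD of at most 0.28, with means of −3.01 for prp-8 and −0.39 for prp-31. Of random lists from the lower table, 1.24 and 0.07 percent were as tight. However, every member had at least 7.05 FPKM with gfp, whereas that table holds 64 values below 1 FPKM, whose ratios can vary more without a pseudocount. The tightness can therefore come from expression level and does not decide for 1 source. The members were seen only because they were selected as lower, and a direct effect of prp-8 RNAi on germ cells would give the same values.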
